A study of Mus musculus with 6 samples.

How the data were processed

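Messenger RNA was measured by RNA sequencing in 6 libraries of mouse mammary organoids, 3 with wild-type Ezh2 and 3 with conditional Ezh2 alleles deleted, all after 8 days in 2 µg/ml doxycycline. Per the labels' protocols, poly(A) RNA was fragmented and reverse transcribed from random hexamers, and the libraries were amplified by PCR. The protocol names no step that marks the strand, so reads of overlapping or antisense genes cannot be assigned with certainty. CASAVA, STAR and the mouse build mm10 are named per the submitters' processing notes. Their versions, the counting tool and the gene annotation are not given in the sources used here.

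The deposited table held 21627 genes with Ensembl identifiers. It gave a raw read count per gene and sample, per the file headers, in whole numbers that summed to between 18292722 and 29203634 per sample. The FPKM columns deposited beside them equalled the count divided by gene length in kilobases and scaled by the total of the same column, with a largest relative difference of 2.1e-07. The authors also gave a signal column per group, the mean normalized count, whose scaling method is not given in the sources used here. The deposited log2 fold change was smaller than the log2 ratio of these means, with a slope of 0.084 for genes with summed means under 20 and 0.818 for summed means over 2000, so it had been shrunken toward 0. The p-value columns and adjusted values come from the authors' own test, whose tool is not given in the sources used here. These columns are quoted only as the authors' deposited table.

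The table held 0 repeated gene identifiers and 0 genes with no count. Of the identifiers, 21407 (98.98%) matched GENCODE release M21, which is annotated on the same build, and the M21 and deposited positions overlapped for 99.97% of them. Gene symbols of 24 genes had been turned into calendar dates in the table and were restored through their identifiers. Transcript length was the median over the basic M21 transcripts of a gene, and GC content was that of its longest transcript.

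Samples were grouped by the genotype in the labels. The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter (a minimum count of 10 and a minimum total of 15), a quasi-likelihood F test with robust dispersion, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values, counts scaled to a common library size, used TMM-scaled library sizes, and group values are mean ± SD over 3 libraries. Fold changes are knockout over wild type on the log2 scale with the standard error (SE) of the fit. The level of Ezh2 was also compared by a two-sided exact permutation test. Intervals and standard errors reflect 3 libraries per group, and PCR copies were not removed by molecular identifiers, so intervals from counts alone cover counting error only.

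A set of 29 gene lists (pathways, cell type markers and gene groups of the tissue) was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. A list needed at least 5 tested members. Members were also counted with p-values adjusted over the list alone. The share of called genes within 10 Mb of Ezh2, leaving out Ezh2, was compared with the rest of the genome by a two-sided Fisher exact test, since DNA beside a targeted allele can come from another strain.

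The genes named are Ezh2, the 12 most raised and 12 most lowered genes past the threshold with a mean CPM of at least 5, groups that do not overlap and an official protein-coding symbol, and up to 4 members of each list with the smallest p. Because edgeR called 0 genes, the rule for the most raised and lowered genes was applied to the calls of DESeq2 1.42.0, a choice made after seeing that count. Some genes that the rule takes are not reported here. The tests, lists, naming rule and the first set of alternatives were chosen before the data were examined.

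The first set of alternatives was DESeq2's Wald test, RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 samples, the replicate number as a block, each library left out in turn, no robust estimation, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) after a filter of 0.5 FPKM in 3 samples, protein-coding genes alone, an adjusted p under 0.01, an adjusted p under 0.05 with an absolute log2 fold change of at least 1, windows of 5 and 20 Mb, an estimated correlation, and fry. Fold changes on the log2(FPKM + pseudocount) scale understate changes of low genes. Alternatives added after seeing the data were an adjusted p under 0.10, genes at an unadjusted p under 0.05 near Ezh2, removal of each library's trend on transcript length, or on length and GC content, with smooth curves in mgcv 1.9.3, and thinning of all libraries to the smallest total. Gene families outside the lists were also chosen after seeing the data.

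The edgeR and DESeq2 steps were tested on simulated data for the 14196 genes tested in the knockout and wild-type comparison, with 100 genes changed at each fold. Means and depths were those of the data, and dispersions were drawn at random around the fitted trend. Each gene had the same dispersion in both groups, although the wild-type libraries differed more among themselves than the knockout libraries did. The rates therefore apply to that simulated spread only. There edgeR recovered 4% of genes changed by 2-fold and 52% of genes changed by 4-fold, with 4 false calls. DESeq2 recovered 40% and 92%, with 81 false calls. Of 100 simulated lists with no change, 1 passed camera's unadjusted test at 0.05. The simulated genes were drawn independently of each other, so this could not test the preset correlation of 0.01. In the real data the estimated correlation was 0.65 for the interferon list and 0.88 for the immune marker list. The length adjustment brought the rank correlation of fold change with length from 0.445 to 0.0106 in simulated data with a trend.

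Libraries of a group were compared by the chi-square of their counts per gene. No pair agreed within sampling noise, so all 6 libraries were counted separately.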

Results

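RNA was sequenced from mammary organoids grown from epithelial cells of female FVB/N mice, aged 8 to 12 weeks, of the MIC line. In this line doxycycline switches on the polyomavirus middle T oncogene and deletes Ezh2 where its alleles are conditional. About 10000 cells were plated, acini formed over 6 days, and the organoids were then kept in 2 µg/ml doxycycline for 8 days with fresh medium every 48 hours. Ezh2 wild-type (WT) and Ezh2 knockout (KO) organoids gave 3 libraries each, and all 6 received doxycycline. The WT libraries held 23437024, 19983015 and 18292722 counts (replicates 1 to 3) and the KO libraries 28632661, 29203634 and 27667054 counts, so every KO library was deeper than every WT library. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. The KO libraries lay close together, with a chi-square per gene of 13.0 to 21.2 between pairs, against 69.3 to 136 between WT pairs. WT replicate 3 was nearer to the KO libraries (47.7 to 65.9) than to the other WT libraries (69.3 and 101).

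Ezh2, which encodes the catalytic subunit of the Polycomb complex that places the repressive histone mark H3K27me3, was lower in every KO library than in any WT library. Its level was 6.75 ± 0.791 CPM in KO and 18.9 ± 3.95 CPM in WT organoids (SD, n = 3 per group), or 35.8% of the WT level. The libraries held 7.13, 7.28 and 5.84 CPM in KO and 19.3, 22.6 and 14.7 CPM in WT. Ezh2 (ENSMUSG00000029687) lies on chromosome 6 from 47530274 to 47595341 in mm10. The log2 fold change was −1.48 ± 0.20 (SE), with a 95% interval of −1.96 to −1.01. The exact permutation test gave p = 0.1, the smallest that 20 arrangements allow. Among 14196 genes the adjusted p was 0.0755 in edgeR and 1.46e-07 in DESeq2, and it ran from 1.46e-07 to 0.407 over 19 alternatives, past the threshold in 3 of them: DESeq2, no filter (0.0190) and without WT replicate 2 (0.0455). The authors' deposited table gave Ezh2 a shrunken log2 fold change of −1.24 with an adjusted p of 2.29e-07. The labels do not name the deleted exons, so reads from outside the deleted part can enter these counts.

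**Figure D1:**
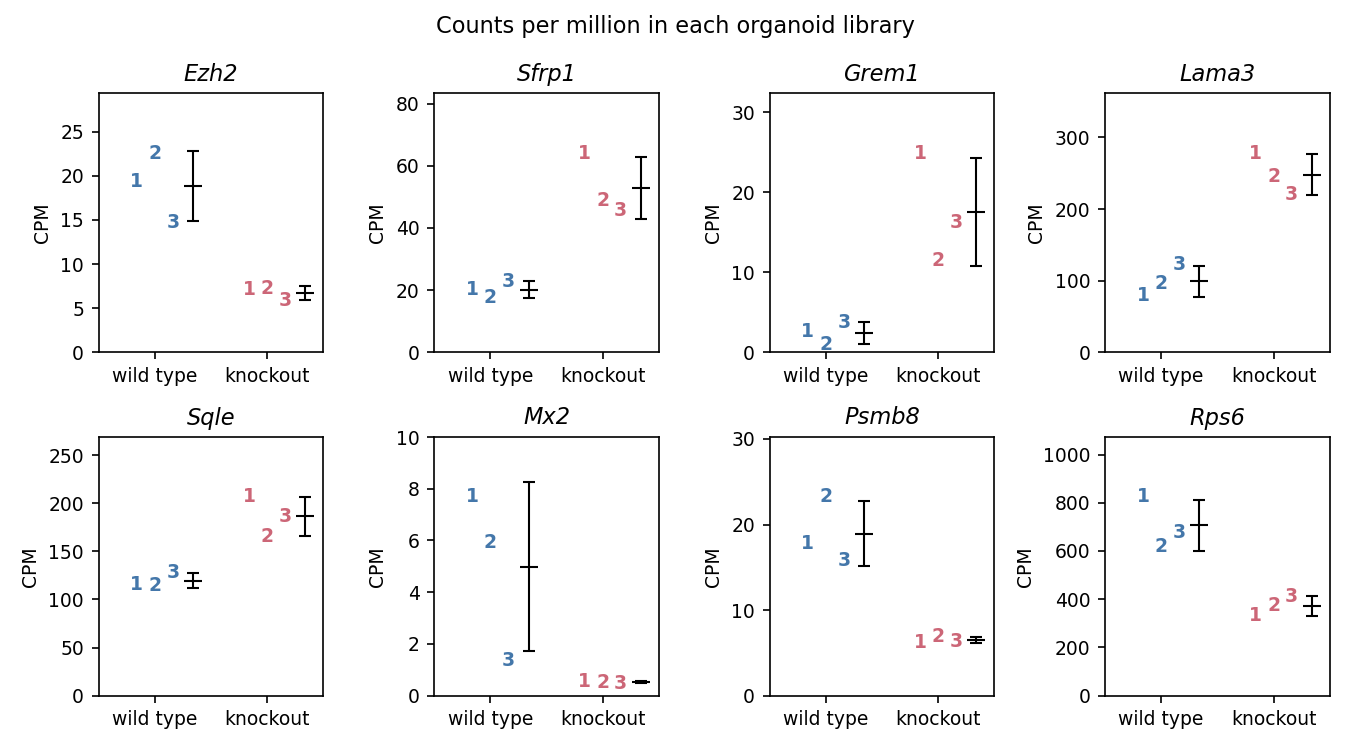
CPM (counts scaled to a common library size, vertical axes from 0) of 8 genes in each WT and KO library, with digits for the replicate and a black mark and bar for the mean and SD of 3 libraries. Ezh2 lies at 5.84 to 7.28 CPM in KO and 14.7 to 22.6 CPM in WT organoids, while Mx2 spreads widely among the WT libraries.

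Among genes past DESeq2's test with a mean CPM of at least 5, those furthest above WT in the KO organoids included Grem1, a secreted BMP antagonist, Ngfr, a neurotrophin receptor, Oxtr, the oxytocin receptor of myoepithelial cells, and Cyp26b1, which degrades retinoic acid. Grem1 averaged 17.6 ± 6.78 CPM in KO and 2.43 ± 1.38 CPM in WT organoids (SD, n = 3 per group), and Oxtr averaged 54.5 ± 13.9 and 16.8 ± 8.29 CPM. Those furthest below included Csn1s1, a milk casein, at 80.1 ± 25.1 CPM in KO and 475 ± 356 CPM in WT organoids (256, 886 and 283 CPM in WT replicates 1 to 3), and the antiviral genes Rsad2, Oasl2, Oas3 and Irf7. These and the other genes named by the same rule passed DESeq2's test and not edgeR's.

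Log2 fold changes of the 12 higher genes under these limits ran from 2.86 ± 0.50 (SE) for Grem1 to 1.52 ± 0.45 for Tenm3, a teneurin of cell adhesion. Between them lay Tnn (tenascin N, 2.42 ± 0.65), Ngfr (1.93 ± 0.30), Dio2 (a thyroid hormone deiodinase, 1.90 ± 0.48), Cyp26b1 (1.71 ± 0.36), Oxtr (1.70 ± 0.35), Fndc1 (1.65 ± 0.57) and Atp6v0a4 (a proton pump subunit, 1.62 ± 0.46). The ETS factor Etv1 (1.60 ± 0.21), Orm2 (1.58 ± 0.17) and the tight junction gene Cldn6 (1.55 ± 0.19) had the smallest errors for their size. The 12 lower genes were Avil (an actin binding protein, −3.92 ± 1.09), Car6 (−3.48 ± 0.90), Rsad2 (−2.90 ± 0.66), Oasl2 (−2.61 ± 0.63), Csn1s1 (−2.57 ± 0.52), Atp6v0e2 (−2.51 ± 0.34), Fcgbp (−2.37 ± 0.53), Irf7 (−2.18 ± 0.52), Phf11d (−2.17 ± 0.46), Chil3 (−2.14 ± 0.47), Gdf15 (−2.14 ± 0.54) and Oas3 (−2.04 ± 0.40). Without WT replicate 1, Avil was at −2.13, the secreted carbonic anhydrase Car6 at −1.91 and the stress cytokine Gdf15 at −1.30, and without WT replicate 2 the mucin-like gene Fcgbp was at −1.54 and Csn1s1 at −1.75 (adjusted p 0.0455 in edgeR). Orm2, Phf11d and Chil3 have close paralogs, so their values are uncertain where reads could be split between copies.

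The edgeR test called 0 of 14196 genes at an adjusted p of 0.05, and DESeq2 called 1046 genes, 564 higher and 482 lower in KO organoids. Of the DESeq2 calls, 850 were also past 0.05 in the authors' deposited table, which holds 858 such genes (460 higher and 398 lower). The smallest adjusted p in edgeR was 0.0755, shared by 47 genes (24 higher and 23 lower), among them Ezh2, Etv1, Orm2, Cldn6 and Atp6v0e2. At an unadjusted p under 0.05 edgeR held 2811 genes, 1267 higher and 1544 lower, where 709.8 would be met by chance. The KO and WT libraries did not overlap for 4086 genes (28.8%) and for 98.3% of the DESeq2 calls. A share of 10% would be met by chance if all 6 libraries spread alike. The WT libraries differed more among themselves than the KO libraries did, so 10% is not a fair reference here. DESeq2 calls genes by their separation in these same libraries, so the 98.3% was largely set by that choice. Leaving out WT replicate 1 gave 38 edgeR calls, of which 33 were DESeq2 calls, and leaving out WT replicate 2 gave 216, of which 182 were; no filter on low counts gave 131.

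Interferon-response genes, which encode antiviral effectors and their regulators, were placed below other genes in the KO organoids by camera (adjusted p 3.97e-16, or adjusted p = 0.518 with an estimated correlation). The antiviral GTPases Mx1 and Mx2 had log2 fold changes of −3.57 ± 0.67 and −3.27 ± 0.63 (SE), and Mx2 averaged 0.515 ± 0.0397 CPM in KO against 4.99 ± 3.28 CPM in WT organoids (SD, n = 3 per group). Of 34 members tested, 33 had negative fold changes, with a median of −1.69 and quartiles of −2.17 and −0.53. Genes of antigen presentation on MHC molecules were lower by camera too (adjusted p 3.19e-08, or adjusted p = 0.210 with an estimated correlation), with a median of −0.48 over 22 members. The immunoproteasome subunits Psmb8 and Psmb9 were at −1.54 ± 0.19 and −1.55 ± 0.24, and Psmb8 averaged 6.50 ± 0.407 CPM in KO and 18.9 ± 3.85 CPM in WT organoids.

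In the interferon list 22 members were lower when adjusted over the list alone, 0 over all genes tested in edgeR and 20 in DESeq2, and all KO libraries lay below all WT libraries for 17 members. Camera's adjusted p for the list ran from 7.51e-49 to 6.42e-09 over 19 alternatives at the preset correlation, and was 0.518 with an estimated correlation. Relative to the KO mean, the list's median was 2.10 in WT replicate 1, 1.71 in WT replicate 2 and 0.36 in WT replicate 3. Isg15, chosen after its values were seen, followed the same order at 22.9, 22.1 and 3.97 CPM, with 3.23, 4.15 and 5.77 CPM in the KO libraries. Ifit3 (−2.02 ± 0.39), which promotes antiviral signalling, has a near-identical copy and is uncertain. The antigen presentation list held 11 lower members when adjusted over the list alone, 0 over all genes tested in edgeR and 9 in DESeq2. Its adjusted p ran from 1.13e-09 to 1.00e-06 in camera over 19 alternatives at the preset correlation, and was 0.210 with an estimated correlation and 0.0269 in fry, which called only this list. Its WT medians were 0.61, 0.57 and 0.53 above the KO mean. The nonclassical MHC genes H2-Q6 (−2.09 ± 0.41) and H2-M3 (−1.41 ± 0.28) were among its lowest members, and H2-Q6 shares reads with close paralogs.

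Markers of immune cells were also lower in KO organoids and stood highest in WT replicate 2. The median of 17 members was −1.60, and all 17 were negative (camera adjusted p 0.000304, or adjusted p = 0.814 with an estimated correlation). Itgam, an integrin of myeloid cells, was at −1.45 ± 0.37 (SE), and Tyrobp, an adaptor of myeloid receptors, at −1.99 ± 0.75, or −0.76 without WT replicate 2. The list's medians relative to the KO mean were −0.26, 2.73 and 0.77 in the WT libraries and −0.24, 0.39 and −0.21 in the KO libraries. The macrophage gene Lyz2, chosen after its values were seen, stood at 78.0, 1277 and 338.7 CPM in WT and 132.5, 171.7 and 101.3 CPM in KO libraries. No member passed when adjusted over the list alone or over all genes tested in edgeR, and 2 passed in DESeq2. Camera's adjusted p ran from 2.40e-10 to 0.220 over 19 alternatives at the preset correlation, and the call was lost without WT replicate 2 (median −0.25, adjusted p 0.220). Without that library the interferon median was −1.58 and the antigen presentation median −0.49.

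**Figure D2:**
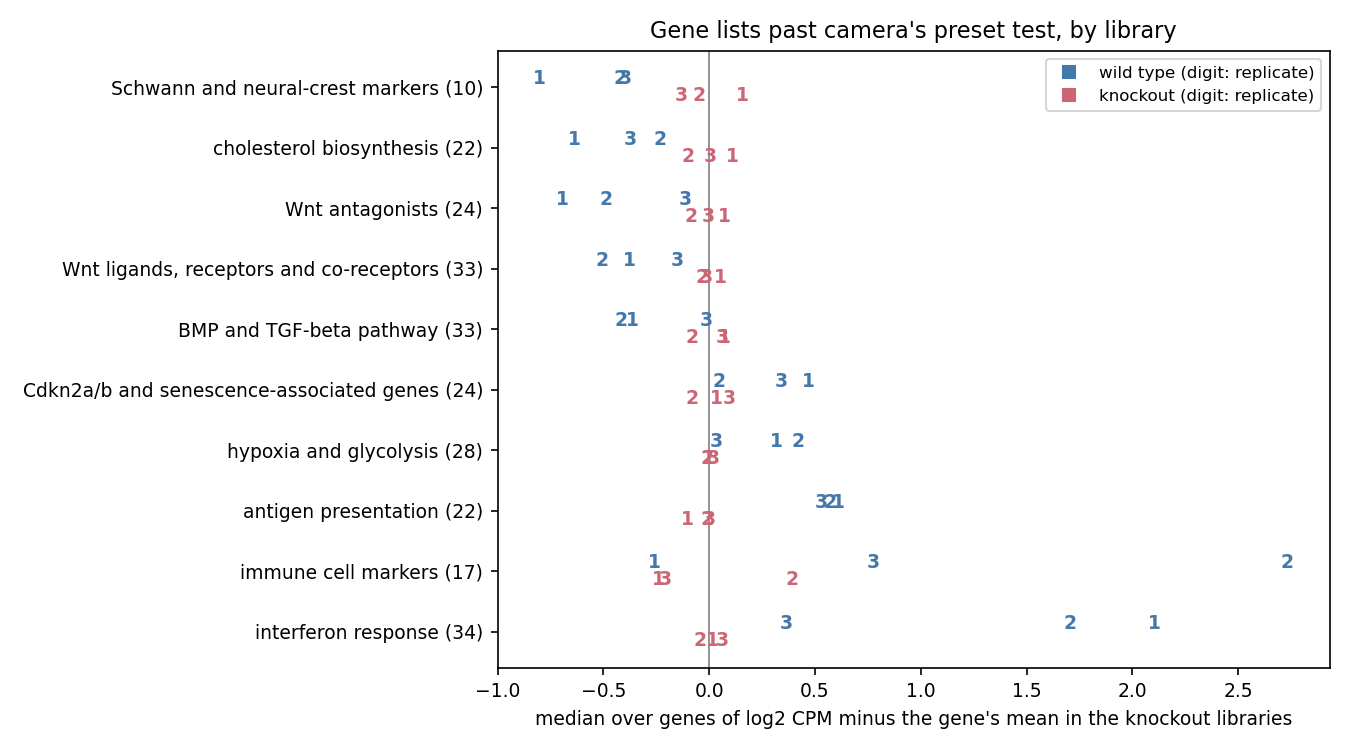
Median over the tested genes of each list (number in brackets) of log2 CPM minus the gene's KO mean, per library, for the 10 lists past camera's preset test. Digits name the replicate, and the immune marker median reaches 2.73 in WT replicate 2 while the antigen presentation medians lie at 0.53 to 0.61 in the WT libraries.

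The series title names the Wnt and mTORC1 pathways. In KO organoids the Wnt co-receptor gene Lrp6, the R-spondin receptor gene Lgr4 and the receptor gene Fzd3 were higher, and so were genes of secreted Wnt antagonists, among them Sfrp1 and Dkk2. Camera's calls of the receptor and antagonist lists were both lost with an estimated correlation (adjusted p = 0.518 for each). Sfrp1 averaged 52.8 ± 9.84 CPM in KO and 20.1 ± 2.65 CPM in WT organoids (SD, n = 3 per group), a log2 fold change of 1.39 ± 0.17 (SE). Lrp6 averaged 276 ± 13.8 and 159 ± 25.6 CPM, a log2 fold change of 0.80 ± 0.14. Rspo1, which encodes a secreted enhancer of Wnt signalling, went the other way at −2.56 ± 0.50. Genes that β-catenin is known to activate had a median of 0.05 (−0.0061 without KO replicate 3).

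Among 33 Wnt ligands, receptors and co-receptors, 9 were higher and 1 was lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 8 and 1 in DESeq2. The median was 0.25, and Lgr4 and Fzd3 were at 0.51 ± 0.09 (SE) and 0.95 ± 0.20. Camera gave an adjusted p of 1.20e-05, from 2.13e-07 to 0.000670 over 19 alternatives at the preset correlation (adjusted p = 0.518 with an estimated correlation). Of 24 Wnt antagonists, 1 was higher when adjusted over the list alone, 0 over all genes tested in edgeR and 4 in DESeq2, with Dkk2 at 2.29 ± 0.58, Sfrp2 at 1.00 ± 0.30 and Dact2 at 0.39 ± 0.11. Their adjusted p was 6.31e-05, from 5.34e-07 to 0.00892 over 19 alternatives at the preset correlation (adjusted p = 0.518 with an estimated correlation), and their median was 0.33, or 0.19 without WT replicate 1 and 0.56 without WT replicate 3. The 25 Wnt target genes held 0 members past either adjustment in edgeR and 1 higher and 1 lower in DESeq2. Their median of 0.05, mean of −0.06 and upward test (adjusted p 0.488, or 0.814 with an estimated correlation) differed in sign, with the receptor tyrosine kinase gene Met at 0.49 ± 0.12 and Myc at −0.72 ± 0.18.

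BMP and TGF-beta pathway genes were higher as a group by camera (adjusted p 0.000368, or adjusted p = 0.636 with an estimated correlation), led by the antagonist Grem1 and by the ligand genes Bmp5 (2.29 ± 0.46, SE, n = 3 per group), Bmp2 (1.37 ± 0.35) and Inhbb (0.80 ± 0.23). The median of 33 members was 0.24, or 0.15 without WT replicate 2 and 0.42 without WT replicate 3. Without WT replicate 3 the medians of the fibroblast and epithelial-mesenchymal transition lists also rose, from 0.06 to 0.47 and from 0.07 to 0.42. Without WT replicate 1 these were at −0.26 and −0.18, with the BMP and TGF-beta median at 0.24. When adjusted over the list alone 2 were higher, 0 over all genes tested in edgeR and 4 in DESeq2. Camera's adjusted p ran from 7.53e-06 to 0.0120 over 19 alternatives at the preset correlation, and was 0.636 with an estimated correlation. In the Notch list of 15 genes the ligand gene Dll1 (0.80 ± 0.24) and the receptor gene Notch2 (0.59 ± 0.18) passed in DESeq2 and 0 passed in edgeR over either set. The Notch median was 0.08 (−0.10 without WT replicate 1 and 0.35 without WT replicate 2), with an adjusted p of 0.306 (0.814 with an estimated correlation).

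Cholesterol biosynthesis genes were higher in the KO organoids by camera (adjusted p 9.44e-09, or adjusted p = 0.518 with an estimated correlation), with Hmgcs1 and Sqle, enzymes of the mevalonate and squalene steps, and Hsd17b7, an enzyme of the later sterol steps, among them. Their log2 fold changes were 0.70 ± 0.14, 0.64 ± 0.12 and 0.57 ± 0.12 (SE, n = 3 per group). Of 22 members 20 were positive, with a median of 0.41. The components of the mTORC1 pathway, the kinase complex that promotes protein synthesis and growth, went both ways, with a median of −0.06 over 60 members. Eif4ebp1, a translation repressor that mTORC1 phosphorylates, was at −0.81 ± 0.15, and Rps6, a ribosomal protein gene, at −0.93 ± 0.15.

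In the cholesterol list 11 members were higher when adjusted over the list alone, 0 over all genes tested in edgeR and 10 in DESeq2. Camera's adjusted p ran from 2.91e-13 to 6.92e-05 over 19 alternatives at the preset correlation, and was 0.518 with an estimated correlation. Of the mTORC1 components 3 were higher and 2 lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 6 and 3 in DESeq2. The insulin signalling genes Foxo1 (0.41 ± 0.09, SE) and Irs1 (0.59 ± 0.14) were among the higher ones. The median of −0.06 (0.08 without WT replicate 1) and mean of −0.02 differed in sign from camera's upward test (adjusted p 0.486, or 0.824 with an estimated correlation). Among 77 genes expressed with mTORC1 activity, 0 passed over the list alone or over all genes tested in edgeR, and 7 were higher and 2 lower in DESeq2. Their median was −0.18 (0.0037 without WT replicate 1 and −0.30 without WT replicate 3), with an adjusted p of 0.564 (0.824 with an estimated correlation). The list shares 8 tested genes with the cholesterol list, Sqle and Hmgcs1 among them, and the cholesterol transporter gene Stard4 in it was at 0.77 ± 0.19. Rps6 has pseudogene copies and is uncertain.

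Among other Polycomb subunit genes Eed, a core subunit, was at −0.38 ± 0.11 and Rbbp4, a histone binding subunit, at −0.29 ± 0.12 (SE, n = 3 per group), and neither passed in edgeR or DESeq2. Of 83 listed developmental regulators that carry H3K27me3 in many tissues, 22 were expressed enough to test, and these went both ways. Of 39 listed HOX genes 21 were tested. The values therefore do not cover listed genes that were too low to test in these libraries. Sim2, a transcription factor gene, averaged 3.60 ± 1.72 CPM in KO and 0.148 ± 0.0903 CPM in WT organoids (SD, n = 3 per group). Cyp26b1 and the homeobox gene Meis1 (0.68 ± 0.20) were higher, and the HOX gene with the smallest p, Hoxa9, was at −1.49 ± 0.58.

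Sim2 had 308 counts in the KO libraries and 9 in the WT libraries (1 to 4 per library), a ratio of rates of 24.7 with a 95% counting interval of 12.8 to 54.5, and its fitted log2 fold change of 4.57 ± 0.59 (SE) had an adjusted p of 0.0755 in edgeR. Of 22 developmental regulators 2 were higher and 1 lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 3 and 1 in DESeq2. Their median of −0.26 (0.03 without WT replicate 1 and 0.06 without WT replicate 3) differed in sign from their mean of 0.08 and camera's upward test (adjusted p 0.486, or 0.824 with an estimated correlation). The 21 HOX genes had a median of −0.34 (−0.19 without WT replicate 1 and −0.66 without WT replicate 2), with 0 past either adjustment in edgeR and 0 in DESeq2. Their adjusted p was 0.436 (0.824 with an estimated correlation), and 0.0124 to 0.808 over 19 alternatives, with the list lower without WT replicate 2 (0.0124). The 11 Polycomb subunit genes had a median of −0.03 (−0.22 without WT replicate 2), an adjusted p of 0.486 (0.814 with an estimated correlation) and 0 calls of any kind.

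No list of mammary lineage genes passed camera, and single members went both ways. Among luminal genes the transcription factor genes Gata3 (0.53 ± 0.09, SE, n = 3 per group) and Tbx3 (0.68 ± 0.15) and also Prom1 (0.76 ± 0.21) were higher. The keratin gene Krt19 (−0.89 ± 0.21) was lower. Among basal genes Lama3, a laminin chain of the basement membrane, averaged 248 ± 28.9 CPM in KO and 99.2 ± 21.7 CPM in WT organoids (SD), a log2 fold change of 1.32 ± 0.18. The integrin gene Itga6 (0.48 ± 0.10) and Oxtr were higher and Cnn1, a contractile gene of myoepithelium (−1.19 ± 0.23), was lower. The casein gene Csn1s1 and the milk peroxidase gene Lpo (−1.13 ± 0.34) were lower, and Btn1a1, a milk fat globule gene (1.02 ± 0.25), was higher.

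Over the 28 luminal genes 2 were higher and 1 lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 4 and 1 in DESeq2. The median of −0.08 (−0.0082 without WT replicate 2 and −0.11 without WT replicate 3) and mean of −0.05 differed in sign from camera's upward test (adjusted p 0.728, or 0.824 with an estimated correlation). Over the 26 basal genes 4 were higher and 1 lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 5 and 1 in DESeq2. Their median of −0.01, which turned to 0.01 with RLE scaling and ran from −0.20 without KO replicate 1 to 0.13 without WT replicate 3, differed in sign from the mean of 0.08 and the upward test, and their adjusted p of 0.236 (0.824 with an estimated correlation) ran from 0.0419 without WT replicate 3 to 0.922 over 19 alternatives. The 17 alveolar and milk genes had a median of −0.17 (−0.43 without WT replicate 1 and 0.32 without WT replicate 2), with 1 higher and 4 lower when adjusted over the list alone, 0 over all genes tested in edgeR, and 1 and 3 in DESeq2. Their adjusted p of 0.436 (0.824 with an estimated correlation) ran from 0.0349 without WT replicate 1 to 0.936 over 19 alternatives. The 15 squamous genes had a median of 0.08 (−0.09 without WT replicate 1 and 0.38 without WT replicate 2), an adjusted p of 0.450 (0.824 with an estimated correlation) and 0 calls in edgeR over either set or in DESeq2. The 34 genes of epithelial-mesenchymal transition had a median of 0.07 (−0.18 without WT replicate 1 and 0.42 without WT replicate 3) and 0 calls in edgeR over either set. Zeb2, a transcription factor gene of that transition, was at −0.45 ± 0.11 (SE) and passed in DESeq2. The adjusted p of that list was 0.486 (0.846 with an estimated correlation), from 0.000107, higher, without WT replicate 3 to 0.985 over 19 alternatives.

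Schwann and neural-crest marker genes were higher in KO organoids by camera (adjusted p 0.000691, or adjusted p = 0.518 with an estimated correlation), with a median of 0.58 over 10 members and with Ngfr and the myelin gene Mbp (0.40 ± 0.11, SE, n = 3 per group) among them. When adjusted over the list alone 2 were higher, 0 over all genes tested in edgeR and 2 in DESeq2. Camera's adjusted p ran from 3.98e-05 to 0.0194 over 19 alternatives at the preset correlation, and was 0.518 with an estimated correlation. The 18 fibroblast genes had a median of 0.06 (−0.26 without WT replicate 1 and 0.47 without WT replicate 3), a mean of −0.27 and a downward test, and Col14a1, a fibril-associated collagen gene (−2.24 ± 0.46), and Pi16 (−1.63 ± 0.36) were lower when adjusted over the list alone and in DESeq2, with 0 in edgeR over all genes tested. The fibroblast adjusted p was 0.816 (0.967 with an estimated correlation), from 0.00337, lower, without WT replicate 1 to 0.969 over 19 alternatives, and 0.0411, higher, without WT replicate 3. Relative to the KO mean, fibroblast medians were −0.99, −0.04 and 0.60 in the WT libraries, and Col1a1, chosen after its values were seen, stood at 562 CPM in WT replicate 1 and at 3708 to 5348 CPM in the other libraries. The 12 endothelial genes had a median of −0.22 (−0.53 without WT replicate 1 and −0.10 without WT replicate 2), an adjusted p of 0.512 (0.824 with an estimated correlation) and 0 calls of any kind. Of the adipocyte markers 4 were expressed enough to test, too few for the list test, with 0 calls. Their median was 0.27, or 0.11 without WT replicate 1 and 0.44 without WT replicate 3.

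Cell cycle genes did not pass as a list and spread widely among the WT libraries. Relative to the KO mean their median was −1.96 in WT replicate 1, 0.91 in WT replicate 2 and −0.35 in WT replicate 3. The proliferation marker Mki67, chosen after its values were seen, stood at 3.20, 60.8 and 19.4 CPM in WT and at 48.9, 52.1 and 30.7 CPM in KO libraries. Camera placed genes of senescence and of hypoxia and glycolysis below other genes in KO organoids, and both calls were lost with an estimated correlation (adjusted p = 0.706 and adjusted p = 0.636). The senescence gene Gdf15 and Car9, a carbonic anhydrase induced by low oxygen (−1.14 ± 0.26, SE, n = 3 per group), were lower in DESeq2.

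The 52 cell cycle genes had a median of 0.07, which turned to −0.01 with upper-quartile scaling, and 0 calls in edgeR over either set or in DESeq2, with the S phase regulator gene E2f1 at 0.34 ± 0.14 (SE). Their adjusted p was 0.103 (0.824 with an estimated correlation), and it ran from 4.67e-12 without WT replicate 2, where the median was 0.95 (−0.34 without WT replicate 1), to 0.582 over 19 alternatives, of which 5 passed upward. The 24 senescence genes had a median of −0.29 and an adjusted p of 0.0169 (0.706 with an estimated correlation), from 0.000106 to 0.245 over 19 alternatives at the preset correlation. Igfbp5, which binds insulin-like growth factors (0.85 ± 0.17), was the 1 member higher when adjusted over the list alone, 0 passed over all genes tested in edgeR, and 1 was higher and 1 lower in DESeq2. The senescence call was lost without WT replicate 1 (0.245, median −0.24) or KO replicate 2 (0.0796, median −0.24). It was also lost after adjustment for transcript length (0.0913) or for length and GC content (0.0701), where the median moved from −0.29 (quartiles −0.48 and −0.20) to −0.19 (quartiles −0.55 and −0.08). The 28 hypoxia and glycolysis genes had a median of −0.29, or −0.18 without WT replicate 2, with 0 past either adjustment in edgeR and 1 higher and 2 lower in DESeq2: the hexokinase gene Hk1 (0.41 ± 0.13), Car9 and the prolyl hydroxylase gene P4ha1 (−0.45 ± 0.11). Their adjusted p was 0.00691 (0.636 with an estimated correlation), from 8.24e-05 to 0.0824 over 19 alternatives at the preset correlation, and the call was lost without WT replicate 1 (0.0824, median −0.22) or WT replicate 2 (0.0603).

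The remaining lists did not pass camera. Of 26 imprinted genes 0 passed in edgeR over either set and 2 were higher and 1 lower in DESeq2, among them the adaptor gene Gab1 (0.41 ± 0.11, SE, n = 3 per group) and the G protein gene Gnas (−0.75 ± 0.20). Their median of 0.02, which turned to −0.02 with upper-quartile scaling and to −0.05 without KO replicate 1, and upward test (adjusted p 0.495, or 0.814 with an estimated correlation) differed in sign from their mean of −0.04. Of 20 stress and immediate early genes, with a median of −0.14 (0.0046 without WT replicate 2), Atf3, a stress-induced transcription factor gene (−0.87 ± 0.20), was lower in DESeq2 and 0 passed in edgeR over either set (adjusted p 0.486, or 0.824 with an estimated correlation). The 12 mitochondrially encoded transcripts had a median of −0.02 (0.35 without WT replicate 2 and −0.37 without KO replicate 2) and a mean of −0.06 against an upward test (adjusted p 0.895, or 0.968 with an estimated correlation) and 0 calls of any kind.

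Short transcripts were lower and long transcripts higher in the KO organoids. Across genes, which are not independent replicates, the rank correlation of log2 fold change with transcript length was 0.457. Genes other than cytosolic ribosomal protein genes had a median log2 fold change of −0.45 for transcripts up to 500 bases and 0.27 for transcripts over 6000 bases. The correlation of each library's deviation with length was 0.33, 0.34 and 0.39 in the KO libraries and 0.0064, −0.48 and −0.21 in WT replicates 1 to 3. With each library's length and GC trend removed, some long genes moved by over 1.5 times: Lrp6 from 0.80 to 0.50, Fzd3 from 0.95 to 0.58, Foxo1 from 0.41 to 0.11, Irs1 from 0.59 to 0.28, Notch2 from 0.59 to 0.24 and Gab1 from 0.41 to 0.25. With that trend removed the Wnt receptor list had a median of 0.20, the Wnt antagonists 0.24, the cholesterol genes 0.44, the interferon genes −1.56 and the antigen presentation genes −0.36. Medians of other lists, not past camera with or without the trend, turned sign. The epithelial-mesenchymal transition list went from 0.07 to −0.04 and the fibroblast list from 0.06 to −0.09. The luminal list went from −0.08 to 0.01, the basal list from −0.01 to 0.05 and mitochondrially encoded transcripts from −0.02 to 0.24.

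**Figure D3:**
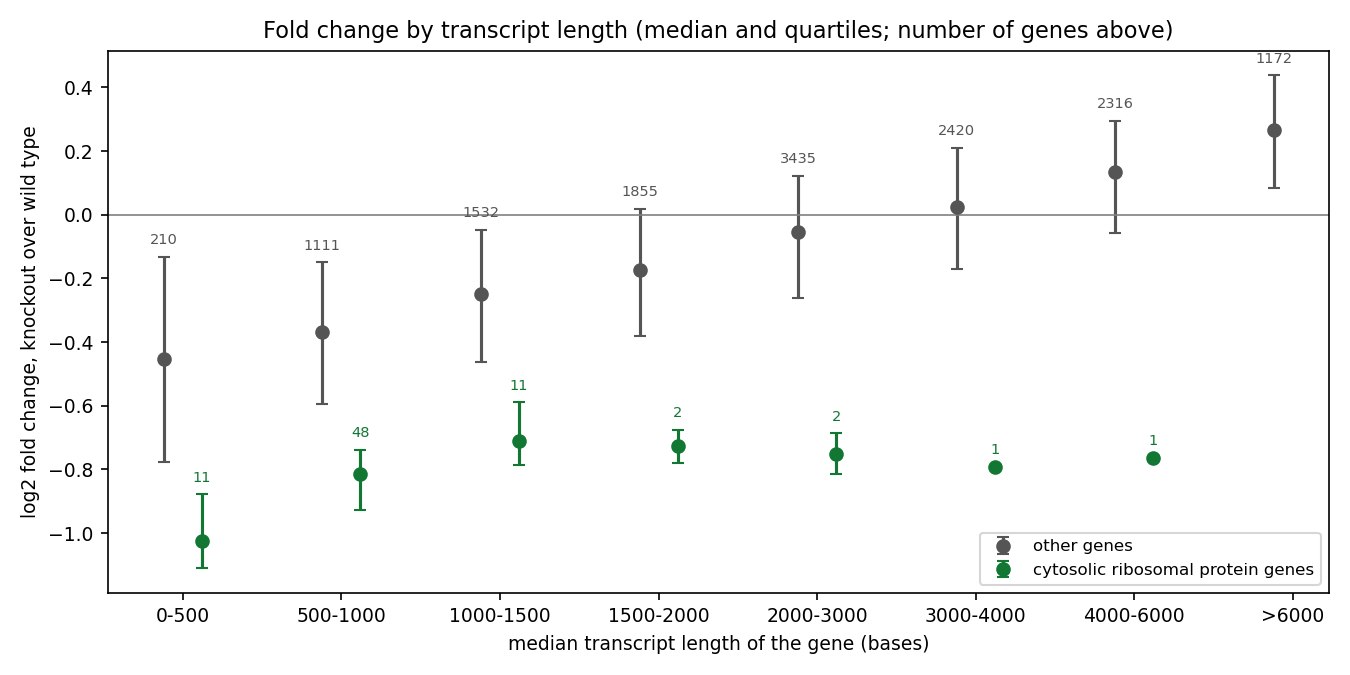
Median and quartiles of the log2 fold change (KO over WT, vertical axis) by transcript length in bases (horizontal axis), with the number of genes above each bar, for cytosolic ribosomal protein genes and all other genes tested. The median of other genes runs from −0.45 in the shortest class to 0.27 in the longest, and that of ribosomal protein genes is −0.82 in the class from 500 to 1000 bases.

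Beside Ezh2 on chromosome 6, Atp6v0e2, a subunit gene of the vacuolar proton pump, was lower in KO organoids, and so was Rarres2, which encodes the chemoattractant chemerin, while Aqp1, a water channel gene, was higher. Atp6v0e2 (48537569 to 48541798 in mm10, 0.977 Mb away) averaged 1.98 ± 0.902 CPM in KO and 11.3 ± 1.06 CPM in WT organoids (SD, n = 3 per group). Rarres2 (−2.77 ± 0.65, SE) lies 1.01 Mb away and Aqp1 (1.93 ± 0.36) 7.78 Mb away, and both were chosen after their values were seen. Within 10 Mb, edgeR called 0 of 115 genes against 0 of 14080 elsewhere, 22 (19.1%) against 2788 (19.8%) at an unadjusted p under 0.05, with Fisher's exact p = 1. DESeq2 called 11 of 115 (9.57%) against 1034 of 14080 (7.34%), with Fisher's exact p = 0.367. Within 5 Mb it called 7 of 52 (13.5%) against 1038 of 14143 (7.34%), with Fisher's exact p = 0.104, and p was 0.577 for 20 Mb. With few genes in these windows, the tests leave a modest gathering of calls open.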

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

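Chosen only after the result was seen were the adjusted p of 0.10, the removal of length and GC trends, the thinning to equal depth and the unadjusted p near Ezh2. Against 0 genes in edgeR, DESeq2 called 1046, no filter on low counts 131, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) 2 each, and an adjusted p of 0.10 gave 374 (188 higher and 186 lower). Leaving out each library gave 0 to 216 genes, with 38 without WT replicate 1 and 216 without WT replicate 2, and the other 15 alternatives gave 0. Against 10 gene lists (5 higher and 5 lower), camera with an estimated correlation called 0 and fry 1, and the other 19 alternatives gave 9 to 13. Near Ezh2, against 0 genes, DESeq2 called 11, no filter 2 and the unadjusted p 22, and leaving out each library gave 0 to 2. The cause of these differences was not tested. Ezh2 stayed lower in all 19 alternatives.

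The 84 other named genes kept their direction in all 1579 values under alternatives. At an adjusted p of 0.05, 80 passed in DESeq2, 19 with no filter, 7 without WT replicate 1 and 22 without WT replicate 2. These genes were chosen from the same data, by DESeq2's call with groups that do not overlap or by the smallest p of their list. Passing in DESeq2 and keeping direction were therefore largely set by that choice. On the log2(FPKM + 1) scale 28 of 78 fold changes were over 1.5 times smaller, by the pseudocount's construction. RLE and upper-quartile scaling shifted the median fold change of all genes by 0.01 and −0.05. At this depth, with the same simulated spread in both groups, edgeR recovered 4% of 2-fold changes. A count of 0 therefore does not exclude changes of that size. In the same simulation DESeq2 made 81 false calls beside 40 true calls at 2-fold and 92 at 4-fold, a larger share than the threshold of 0.05. An unknown part of its 1046 calls, from which named genes were taken, can therefore be false.

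With the replicate number as a block, edgeR called 0 genes and 11 lists, the cell cycle list being added (adjusted p 0.0131), and Ezh2 was at −1.47. The deviations of samples with the same number correlated at −0.07, 0.25 and 0.08, and 3 of 6 samples correlated best with their own number, so no pairing was used. The labels do not say whether a number marks a shared batch. The mitochondrial share of counts was 0.506%, 1.48% and 1.00% in WT replicates 1 to 3 and 0.693%, 1.65% and 1.01% in KO replicates 1 to 3, so a shared batch stays open.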

Other observations

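The gene families, the tests of ribosomal genes and the test of immune cells below were chosen only after the results were seen. Genes of the cytosolic ribosome, which makes protein, had lower levels in KO organoids: all 76 tested had negative fold changes under TMM, RLE and upper-quartile scaling and with any library left out. Their median was −0.82 (quartiles −0.94 and −0.71), and they took 2.93% ± 0.331 of counts in KO and 5.12% ± 0.648 in WT libraries (SD, n = 3 per group). Adjusted over the family alone 75 were lower, with 0 over all genes tested in edgeR and 71 in DESeq2 (camera adjusted p 4.46e-74, or adjusted p = 0.0764 with an estimated correlation). Rps29 was among the lowest at −1.49 ± 0.15 (SE). Mitochondrial ribosomal genes (76, all with negative fold changes) and respiratory chain genes (72, 70 negative) both had a median of −0.37, with 0 and 1 lower when adjusted over the family alone and 7 and 2 in DESeq2 (adjusted p = 0.233 and adjusted p = 0.350 with an estimated correlation). With length and GC trends removed their medians were −0.17 and −0.02, and without WT replicate 2 the respiratory median was −0.15. Proteasome genes (37) had a median of −0.30, with 3 lower when adjusted over the family alone, 2 of them Psmb8 and Psmb9 of the antigen presentation list (family adjusted p = 0.321 with an estimated correlation), and were at −0.07 with the trends removed and −0.14 without WT replicate 2. Semaphorins and plexins (29), which guide cell migration, had a median of 0.23, or 0.46 without WT replicate 3, with 5 higher and 1 lower in DESeq2 and 4 and 1 when adjusted over the family alone (adjusted p = 0.233 with an estimated correlation). Plxna3 and Plxnb1 were higher at 0.90 ± 0.12 and 0.68 ± 0.10, and Plxnc1 was lower at −1.38 ± 0.24. Laminins (11) had a median of 0.25 (adjusted p = 0.332 with an estimated correlation), which turned to −0.08 with the trends removed and to −0.01 without WT replicate 2 and was 0.38 without WT replicate 3.

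Other splits of the 6 samples into groups of 3 number 10 with the real one, too few for a share under 0.05. With a real count of 0 edgeR genes (highest other 0) any split gives as many, so that count tests nothing. Of the 10 splits 4 gave at least the real 10 lists (highest other 16) and 1, the real split, gave the 1046 DESeq2 genes (highest other 20). The split with 16 lists set WT replicates 1 and 2 and KO replicate 3 against the rest.

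The lower level of ribosomal protein genes appeared beside a trend of lower values for short transcripts. Relative to the KO mean, the ribosomal median was 0.94, 0.81 and 0.65 in WT replicates 1 to 3. The length correlations of these libraries were 0.0064, −0.48 and −0.21, which is not the same order. A curve of fold change on length, GC content and level, fitted to other genes, predicted a median of −0.25 for ribosomal protein genes. A median residual of −0.5726 was left, with quartiles of −0.68 and −0.47 and 100% of the residuals negative. This argues against the fitted trend as the whole cause. The 10000 random gene sets gave −0.06 to 0.08, but their genes need not move together as ribosomal genes do. That range is too narrow to judge how unusual the residual is. With the trend removed per library the median was −0.52. Reads lost to pseudogenes would raise these. Of 29 ribosomal pseudogenes 27 had negative fold changes, with a median of −0.6851 and an upper quartile of −0.36, or a median of −0.27 (22 negative) with length and GC trends removed. They took 0.0957% of counts in KO and 0.127% in WT libraries. Reads placed on them could come from the genes themselves, and reads dropped in counting would not appear there. The comparison therefore cannot decide whether shared reads play a part. An effect of the genotype, RNA quality and growth state of the cultures stay open and untested, since WT and KO libraries also differ in depth and in their length trend.

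The lower interferon response could come from immune cells in the WT libraries, above all WT replicate 2, where the macrophage gene Lyz2 stood at 1277 CPM against 78.0 CPM in WT replicate 1. Without WT replicate 2 the immune median was −0.25 while the interferon median was −1.576, which argues against these cells as the whole source. This rests mainly on WT replicate 1, where the interferon median was 2.10 and the immune median −0.26 relative to the KO mean. In WT replicate 3 they were 0.36 and 0.77. The lists share 0 tested genes by their choice, which does not show whether immune cells express the interferon genes. With length and GC trends removed the interferon median was −1.556, which argues against that trend. The list's camera call was lost with an estimated correlation (adjusted p = 0.518), and an effect of the genotype stays open, untested. WT replicate 3 lay only 0.36 above the KO mean, so an interferon episode mainly in WT replicates 1 and 2 stays open. All KO libraries lay below all WT libraries, replicate 3 among them, for 17 of 34 members and for 2069 of 14196 genes tested. WT replicate 3 can therefore share part of the difference.

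Camera placed the lists of Wnt receptors and of Wnt antagonists above other genes in KO organoids, with 9 of 33 and 1 of 24 members higher and 1 and 0 lower when adjusted over the list alone. With length and GC trends removed both lists still passed camera at the preset correlation. The receptor list had an adjusted p of 0.0003468 (median 0.20) and the antagonists 5.13e-05 (median 0.24), while Lrp6 moved from 0.80 to 0.50. The same preset test gave 16 lists in a split that mixed the genotypes. Passing it therefore cannot decide whether that trend is the cause. Neither passed with an estimated correlation (adjusted p = 0.518). An effect of the genotype, untested, and a different mix of cells stay open. Camera at the preset correlation also called the Schwann (adjusted p 0.000691) and immune marker lists (0.000304). Calls of the immune, basal and fibroblast lists changed with the library left out. Both marker calls were lost with an estimated correlation (adjusted p = 0.518 and 0.814). Of 10 Schwann genes 2 passed in DESeq2, and the list does not show which cells express its genes.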
